A study of Mus musculus with 74 samples.

How the data were processed

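RNA from 74 single pro-epicardial cells of Tbx18Cre;mTmG mouse embryos at embryonic day 9.5 was sequenced after full-length amplification (SMART-Seq) and Nextera library preparation. Per the labels, the authors' deposited values are estimated counts per gene, not normalised for depth or gene length. The processing notes name kallisto, without a version, and a human genome build, whereas every gene identifier in the table is a mouse Ensembl identifier. The values are whole numbers, and how they were rounded or summed to genes is not given in the sources used here. Symbols and positions come from GENCODE M21 (GRCm38), which matched 29936 of 30323 identifiers. The 387 without a match held 0.346% of counts.

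All 74 cells had at least 1000 genes with 1 or more counts, so none was left out. Cells were sorted singly, and no doublet caller was run. Total counts ranged from 216177 to 2618538. The labels name no embryo, litter or batch, so cells are not replicates: no test between cells was made, and errors are SD over cells or exact (Clopper-Pearson) 95% intervals for counting cells. Where no cell of the whole sample had a gene, the upper limit is 3 cells of 74, or 4.05%.

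Counts were scaled to CPM and transformed as log2(CPM + 1). A gene was detected in a cell at 5 or more counts. For clustering, 1000 genes of highest variance above a lowess trend (fraction 0.3) were taken from 12304 genes with at least 5 counts in at least 5 cells, then centred and scaled. The first 10 principal components were clustered by Ward's method. The number of clusters was the largest from 2 to 6 in which each cluster held at least 5 cells and the mean silhouette was within 0.02 of the best such number. A cluster was named after a list when at least 3 of its markers were detected in at least 50% of the cells and no leading gene contradicted the name.

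There were 31 fixed gene lists. Lists of cell types covered epicardial, septum transversum, cardiomyocyte, endothelial, erythroid, hepatoblast and foregut, neural crest, leukocyte, smooth muscle and pericyte, and fibroblast genes. Lists of gene groups covered epithelial junction, epithelial-to-mesenchymal transition, extracellular matrix, retinoic acid, BMP, FGF, hedgehog, Notch, Wnt, TGF-beta and PDGF, Hippo, Hox and positional, S-phase, G2/M, glycolysis and hypoxia, and imprinted growth genes. Lists for quality covered dissociation stress, p53 and apoptosis, mitochondrial, housekeeping and sex-linked genes. Xist, H19, Meg3, Muc16 and the mitochondrial ribosomal RNAs were not analysed here, because the table has no line for them, so cells were not sorted by Xist. Each list was read in clusters rebuilt without its genes, at 3 clusters, a choice made after the first clusters were seen. List coherence was the mean pairwise Spearman correlation of members detected in at least 10% of cells, ranked among 10000 random lists matched on mean expression.

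Genes were named by rule. These were 16 regulators, the 3 most abundant members and the least often detected member of each list, the 25 most variable genes, and the 10 genes of highest fold in each cluster. A few list members that the rule names are left out of the text. Variable genes had a mean of at least 10 CPM and were detected in 10% to 90% of cells. Leading genes had a mean of at least 20 CPM and were detected in at least 50% of the cluster's cells. Other members are named where they differed by 2-fold between clusters or were not detected, and were chosen after their values were seen.

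Alternatives changed the detection count to 1 or 10, the pseudocount to 10 CPM, the scaling to scran pooled size factors, the variable genes to 500 or 2000, the components to 5 or 20, the share of cells for list members to 25%, the minimum of genes per cell to 3000, and the clustering to k-means. Others used no filter on low counts, left out cell cycle genes, clustered the genes in 2 random sets of equal size, or thinned every cell to 354002 counts, which left out 8 shallower cells. The procedure was tested on simulated data with 200 changed genes among 12304. At 3 clusters the adjusted Rand index with the planted groups was -0.009 without a change, 0.694 at a 2-fold change and 1 at a 4-fold change. The rule for the number of clusters chose 5 clusters without a change, where the best mean silhouette was 0.089, 5 at a 2-fold change and 3 at a 4-fold change, so it can give clusters where none were planted. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, scikit-learn 1.9.0, statsmodels 0.14.6, matplotlib 3.10.9, R 4.3.3 and scran 1.30.0 were used.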

Results

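The transcriptomes of 74 single cells from the mouse pro-epicardial organ were measured at embryonic day 9.5. The pro-epicardial organ is a transient cluster of mesothelial cells at the inflow side of the looping heart, from which the epicardium arises. Cells were sorted after dissociation from C57BL/6 embryos that carried a Tbx18-driven Cre recombinase and a two-colour membrane reporter, so every cell came from the Tbx18 lineage by design. The series addresses how heterogeneous these cells are, and its labels hold a single group without treatment or control. The labels name no embryo or litter, so the 74 cells were treated as 1 sample. No test between cells or clusters was made and no p-value is given. Errors are standard deviations (SD) over cells or exact 95% binomial (Clopper-Pearson) intervals. These intervals cover only the counting of cells and not differences between embryos. Reads without molecular identifiers are also not independent molecules.

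The median cell held 849718 estimated counts, with a range from 216177 to 2618538. A median of 9369 genes had at least 1 count, with a range from 7828 to 11337, and a median of 7858.5 genes had at least 5 counts, the level at which a gene was called detected. The 10 most abundant genes of a cell took a median of 5.49% of its counts, and mitochondrially encoded genes took 2.02% (range 0.753% to 4.43%). No pair of cells had identical values. Expression is given as CPM, each gene's count scaled to the same total in every cell.

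Transcripts of Tbx18, Tcf21 and Wt1, transcription factors of the pro-epicardium, were found in most sorted cells. Tbx18, the driver of the reporter (ENSMUSG00000032419, chromosome 9, 87702800 to 87731260, GRCm38), was detected in 69 of 74 cells (93.2%, interval 84.9% to 97.8%) at 191 ± 114 CPM (mean ± SD over 74 cells). Tcf21, a basic helix-loop-helix factor of epicardium-derived fibroblasts (ENSMUSG00000045680, chromosome 10, 22817281 to 22820174), was detected in 63 cells (85.1%, interval 75.0% to 92.3%). Wt1, the Wilms tumour zinc-finger factor of mesothelia (ENSMUSG00000016458, chromosome 2, 105126529 to 105173616), was detected in 60 cells (81.1%, interval 70.3% to 89.3%). Gata4, a cardiac and mesodermal GATA factor, was present in all 74 cells at 541 ± 188 CPM, and Pdgfra, Gata5, Tbx5 and Hand2 were present in 71, 68, 67 and 65 cells. The epicardial guidance cue Sema3d was detected in 57 cells, the T-box factor Tbx20 in 50 and the zinc-finger factor Bnc1 in 43. Of the 16 regulators, 11 were detected in at least 50% of cells.

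The remaining 5 regulators were found in fewer cells. The tendon and pro-epicardial factor Scx was detected in 35 cells (47.3%, interval 35.6% to 59.3%) and the mesothelial uroplakin Upk3b in 34 (45.9%, interval 34.3% to 57.9%). Aldh1a2, which makes retinoic acid, was detected in 18 cells (24.3%, interval 15.1% to 35.7%), and its mean of 29.3 CPM had an SD of 82.6. The second heart field factor Isl1 was detected in 14 cells (18.9%, interval 10.7% to 29.7%), and the cardiac homeobox factor Nkx2-5 in 5 (6.76%, interval 2.23% to 15.1%). The reporter sort selects for a history of Tbx18 activity, so these shares describe sorted cells and not the whole organ.

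**Figure D1:**
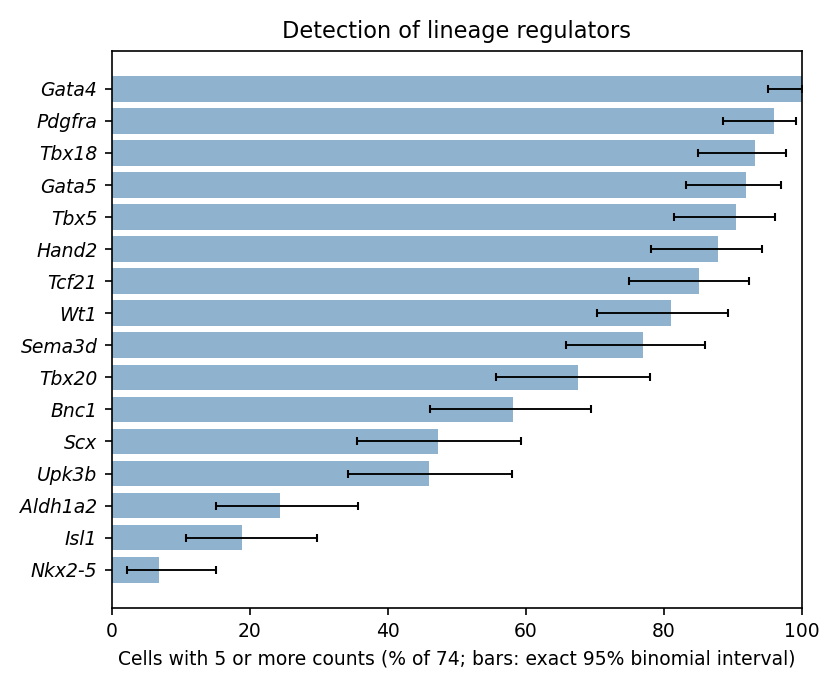
Share of the 74 sorted cells (x axis, percent) in which each of 16 lineage regulators (y axis) had at least 5 estimated counts. Lines are exact 95% binomial intervals for counting cells; shares run from 6.76% for Nkx2-5 to 100% for Gata4.

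Scx and Sema3d, which have been used to mark separate pro-epicardial compartments, were found in overlapping sets of cells. Both were detected in 32 cells, Scx alone in 3, Sema3d alone in 25 and neither in 14, against 27.0 cells with both if the genes were detected independently. Every Scx-positive cell also had Tbx18 and Tcf21. Wt1 and Tcf21 were detected together in 56 cells, against 51.1 under independence. Over all 15 pairs of Tbx18, Wt1, Tcf21, Scx, Sema3d and Aldh1a2, the observed number of cells with both genes was 1.01 to 1.19 times the number under independence. After every cell was thinned to 354002 counts, which left out 8 shallower cells, the Scx and Sema3d ratio was 1.19 and that of Wt1 and Scx was 1.25. For Tbx18 and Aldh1a2 it was 0.999.

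The cells fell into 3 clusters of 33, 31 and 10 cells, which were 44.6% (interval 33.0% to 56.6%), 41.9% (interval 30.5% to 53.9%) and 13.5% (interval 6.68% to 23.5%) of the sample. Cluster 2 was compact, with a mean silhouette of 0.505 and no cell of negative silhouette. Cluster 1 had a mean silhouette of 0.0310 with 8 cells below 0, all of them nearer to cluster 2 than to cluster 3. Cluster 3 had 0.132 with 2 cells below 0, of which 1 was nearer to cluster 1 and 1 to cluster 2. Median totals were 901464, 788465 and 839707 counts in clusters 1, 2 and 3. Other settings gave between 2 and 6 clusters, and the thinned counts gave 2. When 3 clusters were asked for, the index of agreement with the clusters used here (adjusted Rand index, 1 for identical groupings) was 0.602 after thinning.

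**Figure D2:**
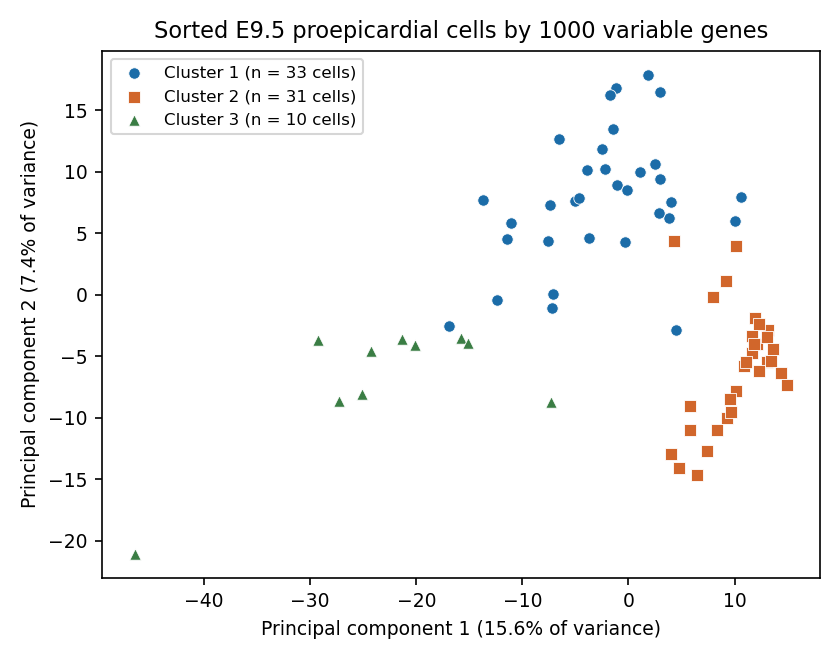
Position of each of the 74 cells on the first 2 principal components (axes, arbitrary units, with the percent of variance of the 1000 most variable genes in each label), coloured by cluster. Most of the 31 cells of cluster 2 group together at the right, and the 33 cells of cluster 1 lie next to the 10 cells of cluster 3.

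The marker lists used to name clusters, and the other gene lists, were fixed before the data were examined. Cluster 2 was defined by Lhx9, Vwa1, Tm4sf5, Ppp1r16b, Hpgd, Tubb3, Upk1b, Apela, Scrn1 and Itga4. It had 17 of 23 epicardial markers in at least 50% of its cells and was called epicardial-like. In cluster 2, 11 of 18 septum transversum, 8 of 12 fibroblast, 5 of 18 cardiomyocyte and 4 of 17 endothelial markers also passed that mark. Its leading genes included Tubb3, a tubulin of neurons. Cluster 3 was defined by Myh6, Csrp3, Ankrd1, Tnnc1, Rgs4, Apobec2, Ramp1, Coro6, Myo18b and Casq1, had 13 of 18 cardiomyocyte markers in at least 50% of its cells and was called cardiomyocyte-like. In that cluster 12 of 18 septum transversum, 9 of 23 epicardial, 4 of 12 smooth muscle and 4 of 12 fibroblast markers passed too. The counts alone thus do not single out a name. Among the leading genes, Myh6, Csrp3 and Tnnc1 of cluster 3 are on the cardiomyocyte list. In cluster 2 only Upk1b is on the epicardial list, so that name rests mainly on the count of markers. Cluster 1 was defined by Lhx2, Shisa3, Tmem119, Pdgfrb, Cyp1b1, Col1a1, Selenbp1, Tnc, Tgfbi and Mmp2. These include a marker each of the septum transversum, pericyte and fibroblast lists, and 12 of 18 septum transversum and 11 of 23 epicardial markers were in at least 50% of its cells, so it was left unnamed. To keep a list's genes from defining the groups in which they were read, each list below was read in clusters rebuilt without it. A member was called higher or lower at a 2-fold difference in mean CPM between a cluster and all other cells, a rule of size and not a test. It was applied to members detected in at least 10% of cells. The share of all genes that pass this rule was not counted, so the counts of members are not set against a background.

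Without the 16 regulators the clusters were identical, at 33, 31 and 10 cells. In the epicardial-like cluster Wt1 and Tcf21 were detected in 31 of 31 cells, at 166 ± 65.1 and 308 ± 182 CPM, and Bnc1 in 31 of 31. Scx was found in 28 of its 31 cells, against 7 of 33 in cluster 1 and 0 of 10 in cluster 3. Upk3b was found in 29, 4 and 1 cells in the order of clusters 2, 1 and 3. In cluster 1 Tbx18 was detected in 31 of 33 cells at 161 ± 110 CPM and Wt1 in 26 at 43.6 ± 44.6 CPM, and Gata5 was higher there at 295 ± 171 CPM against 98.8 ± 124 in cluster 2. In cluster 3 Tbx18 was detected in 7 of 10 cells, Wt1 in 3 and Tcf21 in 3. Tbx20, Tbx5 and Isl1 were higher in that cluster, at 124 ± 72.5, 214 ± 93.1 and 142 ± 160 CPM. Aldh1a2 was found in 9 of 33, 9 of 31 and 0 of 10 cells of clusters 1, 2 and 3.

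Most epicardial genes were higher in the epicardial-like cells. In clusters of 34, 31 and 9 cells rebuilt without the epicardial list, 14 of 21 measured members were higher in cluster 2 and 3 were lower, namely Aldh1a2, Tbx20 and Gata5. The sialomucin Podxl was at 820 ± 355 CPM in cluster 2 against 102 ± 221 in cluster 1 and 74.7 ± 66.7 in cluster 3. The membrane-cytoskeleton linker Ezr was at 705 ± 332, 122 ± 139 and 46.2 ± 39.7 CPM in the same order, and the keratin Krt8 at 385 ± 166, 216 ± 195 and 147 ± 109. Lrrn4, a mesothelial marker, was detected in 31 of 31, 16 of 34 and 0 of 9 cells. In cluster 3, 18 of the 21 members were lower and Tbx20 was higher. The median list level, a mean of log2(CPM + 1) over members, was 3.32, 5.61 and 2.31 in clusters 1, 2 and 3. Msln, the mesothelin gene of adult mesothelium, was detected in 1 of all 74 cells. Of 11 measured members of the epithelial junction list, 5 were higher in cluster 2, namely Krt7 and the epicardial-list genes Krt18, Krt19, Ezr and Podxl, and the desmosomal genes Dsp and Pkp2 were higher in cluster 3 and lower in cluster 2. The epithelial cadherin Cdh1 was detected in 1 cell and the tight junction gene Cldn7 in 0 of 74.

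**Figure D3:**
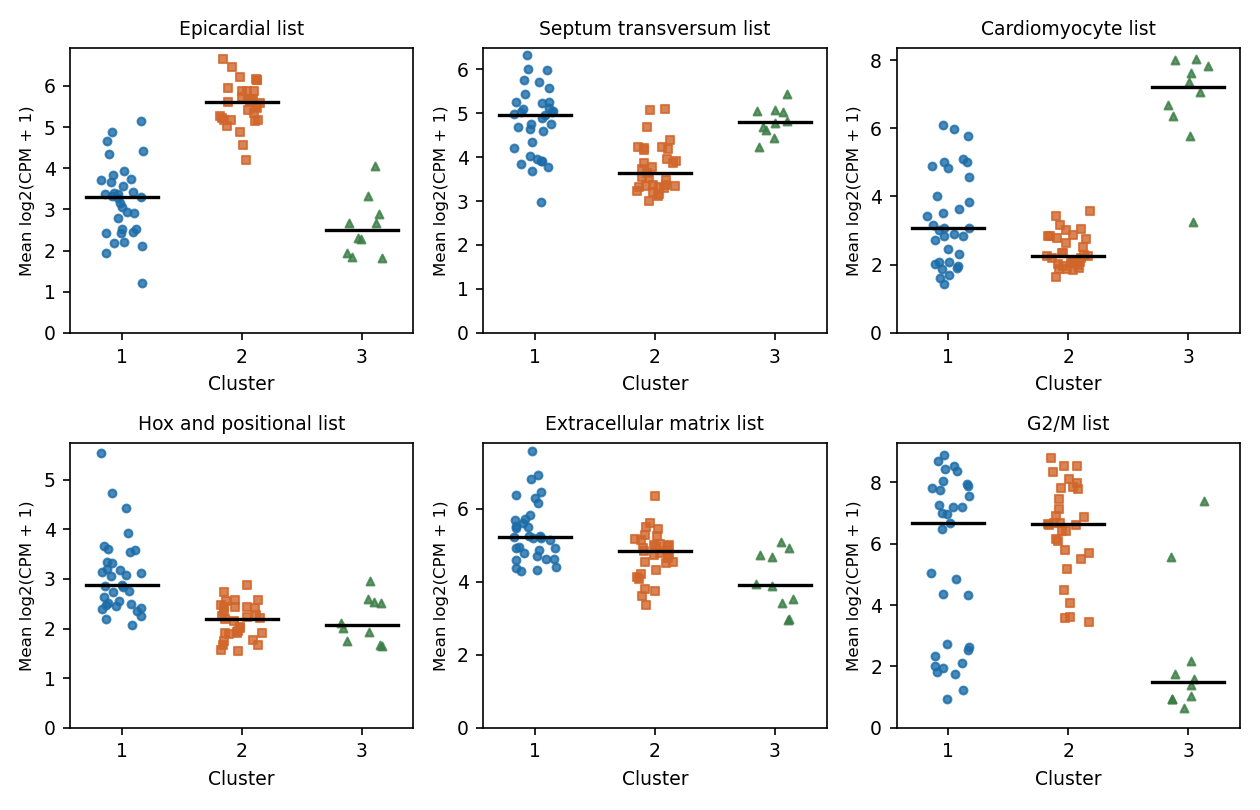
Level of 6 fixed gene lists in each cell, as the mean of log2(CPM + 1) over the list's members (y axis), by cluster (x axis; 33, 31 and 10 cells). Points are cells and black lines are medians; the epicardial list is highest in cluster 2 and the cardiomyocyte list in cluster 3, where the G2/M list is lowest.

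Sarcomere transcripts marked the cardiomyocyte-like cells, and lower levels were present elsewhere. In clusters of 33, 33 and 8 cells rebuilt without the cardiomyocyte list, 14 of 14 measured members were higher in cluster 3. Cardiac actin Actc1 was at 15688 ± 9912 CPM there, against 945 ± 1900 in cluster 1 and 471 ± 2167 in cluster 2. Without the highest Actc1 cell of each, which came from the cardiomyocyte-like cluster of the full clustering, these were 699 ± 1286 and 96.3 ± 234 CPM. The median of Actc1 was 13374 CPM in cluster 3, 57.1 in cluster 1 and 13.9 in cluster 2. The means outside cluster 3 thus came from a part of the cells and not from a like level in all. The atrial light chain Myl7 was at 7343 ± 5405, 744 ± 967 and 1114 ± 1520 CPM, and slow skeletal troponin Tnni1, expressed in the embryonic heart, at 3487 ± 709, 1524 ± 826 and 1084 ± 522. The myosin heavy chain Myh6 was detected in 7 of 8 cells of cluster 3, 11 of 33 of cluster 1 and 3 of 33 of cluster 2. Over all 74 cells, Tnni1 and Myl4 were detected in every cell, Tnnt2 in 73 and Myl7 in 72. Pln, the phospholamban gene, was detected in 1. Nppa, the atrial natriuretic peptide gene, was found in 3 cells, all in cluster 1. In clusters of 35, 31 and 8 cells, smooth muscle genes were lower in the epicardial-like cluster for 8 of 8 measured members. The smooth muscle actin Acta2 was at 181 ± 232 CPM in cluster 2, 1031 ± 1370 in cluster 1 and 6414 ± 3080 in cluster 3, and Tagln and Cnn1 were likewise higher in cluster 3. In cluster 1 the receptor Pdgfrb, Mylk and Rgs5 were higher. The cofactor Myocd was higher in both, at 121 ± 109 CPM in cluster 3 and 56.5 ± 59.7 in cluster 1. Cspg4 was detected in 1 cell.

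Of 16 measured septum transversum members, 9 were lower in cluster 2 and none higher, in clusters of 35, 31 and 8 cells. In cluster 3, 5 were lower, namely Foxf1, Hlx, Lhx2, Alcam and Hand1, and 5 were higher, namely Wnt2, Bmp4, Des, Isl1 and Tbx5. The LIM homeobox factor Lhx2 was detected in 19 of 35, 7 of 31 and 1 of 8 cells of clusters 1, 2 and 3, and the forkhead factor Foxf1 in 15, 3 and 1 cells. Hlx, Alcam, Des, Nr2f1 and Hand1 were also higher in cluster 1. Bmp4 was at 1157 ± 437 CPM in cluster 3, 152 ± 230 in cluster 1 and 22.7 ± 28.9 in cluster 2. Gata4, Wnt2 and Gata6 were the most abundant members, and Foxf2 was detected in 2 cells. Extracellular matrix genes were higher in cluster 1 for 6 of 18 members, namely Col1a1, Col3a1, Col5a1, Col6a1, Nid1 and Tnc, with Col4a2 lower. Col3a1 was at 517 ± 510, 228 ± 294 and 34.6 ± 40.8 CPM in clusters 1, 2 and 3, and Sparc, the most abundant member, at 482 ± 227, 500 ± 128 and 364 ± 209. Fibronectin Fn1 was detected in all 74 cells, and Col4a1 in 33. In cluster 3, 9 of the 18 were lower, whereas Vcan and Lamc1 were higher. Of 9 fibroblast markers, Col1a1 and Col3a1 were higher in cluster 1, Dcn was higher in cluster 2, and 6 were lower in cluster 3. Vim and Col1a2 differed by less than 2-fold, and Thy1 was detected in 0 of 74 cells. Among regulators of epithelial-to-mesenchymal transition, Snai1, Snai2, Twist2 and Tgfbr3 were higher in cluster 1 and Tcf21 and Sox9 in cluster 2, where Sox9 was at 482 ± 234 CPM against 90.7 ± 181 in cluster 1. Prrx1 was detected in 5 of 74 cells.

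**Figure D4:**
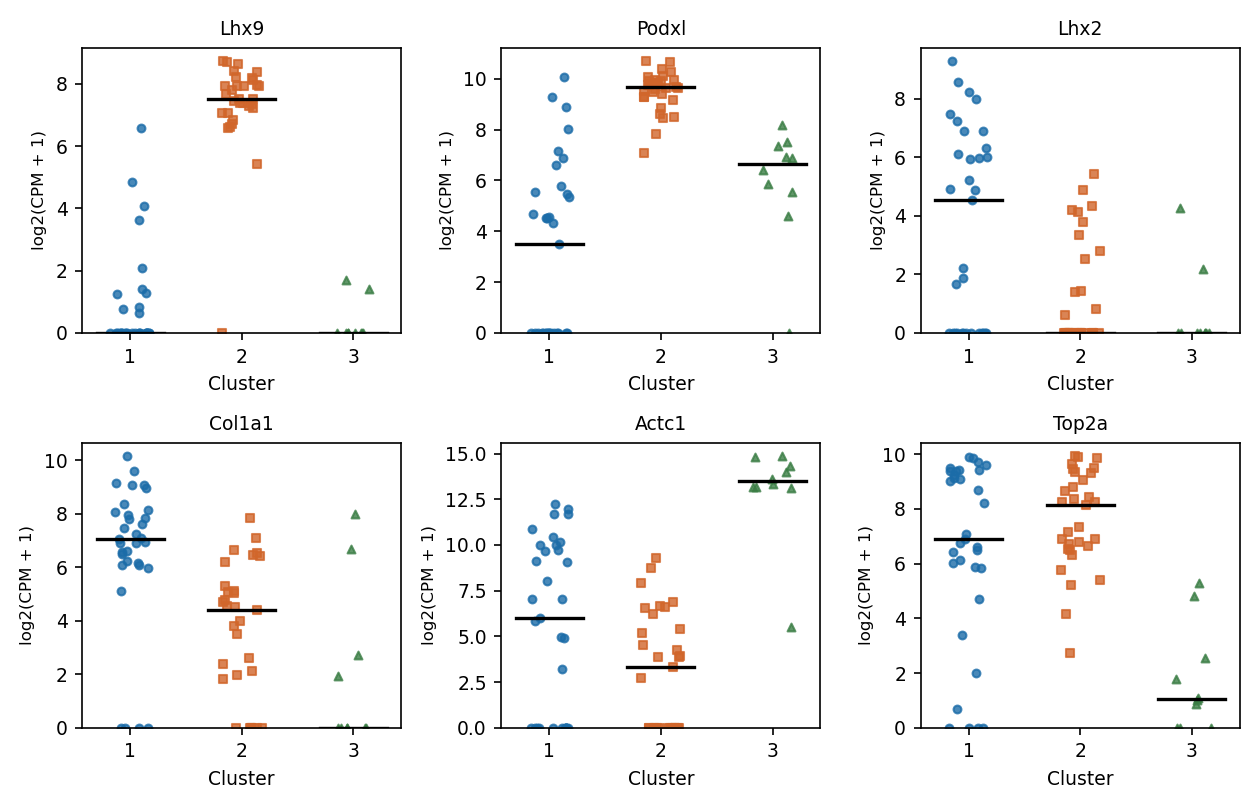
Expression of 6 genes in each cell as log2(CPM + 1) (y axis) by cluster (x axis; 33, 31 and 10 cells). Points are cells and black lines are medians; Lhx9 and Podxl are highest in cluster 2, Actc1 in cluster 3, and Lhx2 and Col1a1 are spread within cluster 1, while Top2a is low in most cells of cluster 3.

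Positional genes differed between clusters 1 and 2. Leaving the Hox and positional list out of the clustering moved no cell. Of 12 measured members, Hoxa2, Hoxb1, Hoxb2, Hoxb4 and Hoxb5 were higher in cluster 1, and 6 were lower in cluster 2. Hoxb2 was detected in 31 of 33, 24 of 31 and 7 of 10 cells of clusters 1, 2 and 3, and Hoxb1 in 12, 1 and 1 cells. Meis2 was detected in 27 of 33, 30 of 31 and 1 of 10 cells. Meis1 and Tbx5 were the most abundant members, and Hoxb6 was detected in 1 cell.

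Retinoic acid, BMP and Wnt lists each held members that differed at least 2-fold between a cluster and the remaining cells. The cluster sizes for the retinoic acid, FGF, hedgehog, Notch, Wnt and Hippo lists were 33, 31 and 10 cells. Retinoic acid genes were higher in cluster 1 for Aldh1a2, Rdh10, Rarb and Crabp1 and in cluster 2 for Aldh1a1 and Aldh1a3, both also retinaldehyde dehydrogenases, and 5 of 10 measured members were lower in cluster 2. For Aldh1a2 the higher mean, 53.1 ± 117 CPM, came from few cells, since it was detected in 9 of 33 cells there. Aldh1a1 was detected in 17 of 31 cells of cluster 2 and 1 of 33 of cluster 1. In cluster 3, 7 of 10 measured members were lower. Crabp2 was the most abundant member, at 286 ± 168 CPM in cluster 3 and 77.1 ± 79.0 in cluster 2. The degrading enzyme Cyp26a1 was detected in 0 of 74 cells, which allows a share of up to 4.05%. Of the BMP list, Bmp2, Bmp4 and Bmp7 were higher in cluster 3, and the antagonist Nog was detected in 15 of 31 cells of cluster 2 and 2 of 35 of cluster 1. The response genes Id3, Id2 and Bambi were the most abundant members and were detected in all cells, and the antagonist Grem1 was detected in 3. Of the Wnt list, Wnt2 was at 1126 ± 602, 434 ± 452 and 222 ± 219 CPM in clusters 3, 1 and 2. Wnt5a and Wnt2b were higher in cluster 2 and the inhibitors Sfrp1 and Dkk1 in cluster 1. Ctnnb1, at 507 ± 155 CPM, and Sfrp5, at 481 ± 407 CPM, were the most abundant members, Sfrp5 was lower in cluster 1, 7 of 17 members were lower in cluster 3, and Wnt9b was detected in 0 cells.

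Members of other pathways also differed between clusters. Of the FGF list, Fgfr1 was higher in cluster 1, at 60.1 ± 35.0 CPM against 16.9 ± 20.1 in cluster 2, Fgf9 and Spry1 were higher in cluster 2, and 3 of 10 members were lower in cluster 3. Dusp6 and Fgfr2 were the other abundant members, and Fgf2 was detected in 0 of 74 cells. No hedgehog member was higher in any cluster, and Smo and Gli1 were lower in cluster 3. Smo was detected in 73 cells, Gli3 in 65, Sufu in 52 and the ligand gene Shh in 0. Notch2, Notch3 and Rbpj were higher in cluster 1, and these and Hes1 were lower in cluster 2. Hey1, a Notch target, was at 247 ± 131 CPM in cluster 2 and 135 ± 112 in cluster 1, Hes1 was detected in 51 cells and the ligand gene Dll1 in 0. Of the TGF-beta and PDGF list, Tgfbr2, Tgfbr3 and Pdgfrb were higher in cluster 1 and Tgfb3 and Acvr1 in cluster 2. In cluster 3, 6 of 10 members were lower and Pdgfa was higher. Tgfb2 was detected in all 74 cells at 343 ± 185 CPM, Tgfbr1 in 72, and Pdgfb in 0. Of the Hippo list, the YAP and TAZ target Ccn2 was at 599 ± 598 CPM in cluster 2 and 50.2 ± 84.8 in cluster 1, and Wwtr1, which encodes TAZ, was also higher in cluster 2. Ankrd1 was higher in cluster 3, at 1528 ± 2558 CPM, Ccn1 was the most abundant member and Sav1 was detected in 23 cells.

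Proliferation genes were detected in most cells. At least 5 of 20 S-phase genes were detected in 74 of 74 cells. At least 5 of 20 G2/M genes were detected in 68 of 74 (91.9%, interval 83.2% to 97.0%), and in 60 of 66 cells (90.9%) after thinning. In the clusters of all genes this was 31 of 33, 31 of 31 and 6 of 10 cells, and after thinning 29 of 31, 26 of 26 and 5 of 9. In clusters of 34, 31 and 9 cells rebuilt without the G2/M list, 19 of 20 members were lower in cluster 3. Topoisomerase Top2a was at 5.42 ± 12.5 CPM there, against 318 ± 330 in cluster 1 and 342 ± 310 in cluster 2, and Ccnb1 at 138 ± 368, 372 ± 471 and 459 ± 403. The size of this difference depended on which genes defined the clusters. In clusters found without all genes that follow the cycle score, 14 of 20 G2/M members were lower in cluster 3, where 8 of 12 cells had at least 5 G2/M genes. There Top2a was at 102 ± 213 CPM, against 327 ± 353 in cluster 1 and 326 ± 295 in cluster 2. With only the list left out, Ube2c was at 49.4 ± 133 CPM in cluster 3, and Kif11 was detected in 1 of its 9 cells. Of the S-phase genes, 15 of 20 were lower in cluster 3, in clusters of 37, 30 and 7 cells. The helicase subunits Mcm7, Mcm6 and Mcm2 were the most abundant, and Ung was detected in 36 of 74 cells.

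At least 3 markers of the leukocyte, hepatoblast or neural crest list were found in few cells, and at least 3 endothelial or erythroid markers in more. No cell had 3 or more of 11 leukocyte markers, which allows a share of up to 4.05%; Csf1r was detected in 4 cells, Ptprc in 2, Fcgr1 in 1 and Tyrobp in 0. Of 15 hepatoblast and foregut markers, 3 or more were detected in 6 cells. Alb was detected in 20, Prox1 in 12, Apoa2 in 9 and Hnf4a in 0. The 3 measured members, Alb, Apoa2 and Prox1, were higher in cluster 3 and lower in cluster 2, with Alb at 24.6 ± 42.6 CPM in cluster 3, 13.5 ± 43.5 in cluster 1 and 5.35 ± 12.9 in cluster 2. Without the highest Alb cell of each cluster these were 12.0 ± 15.6, 7.28 ± 25.1 and 3.34 ± 6.49 CPM, so each mean leaned on 1 cell. Of 10 neural crest markers, 3 or more were detected in 8 cells; Ets1 was detected in 50 cells, Erbb3 in 14, Sox10 in 8 and Foxd3 in 0. Sox10 and Erbb3 were higher in cluster 2, and Ets1 was lower in cluster 3. Of 17 endothelial markers, 3 or more were detected in 60 cells. Over all 74 cells, Egfl7 was detected in 67, the pan-endothelial gene Pecam1 in 62 at 16.6 ± 12.5 CPM, Tek in 52 and Flt1 in 26, and the pan-endothelial genes Cdh5 and Cldn5 in 0. The receptor gene Flt1 was at 53.6 ± 53.3 CPM in cluster 2 and 2.29 ± 7.54 in cluster 1. Of 13 erythroid markers, 3 or more were detected in 28 cells, with the adult globin genes Hba-a2, Hbb-bs and Hba-a1 in 45, 34 and 30 cells. Hba-a2, Hbb-bs and Hbb-bt were higher in cluster 1 by the 2-fold rule, and its cell 17 had the highest level of each. Hba-a2 was at 67.2 ± 188 CPM there, against 33.1 ± 63.5 in cluster 2 and 33.0 ± 47.7 in cluster 3. Without cell 17 it was at 36.5 ± 65.3 CPM in cluster 1 and no longer 2-fold higher. Without cell 41 it was at 19.7 ± 23.4 CPM in cluster 3. Hbb-bs and Hbb-bt were not read by cluster without cell 17. Of the sex-linked genes, the Y-linked demethylase genes Kdm5d and Uty were detected in 31 and 11 cells, Eif2s3y in 1 and Ddx3y in 0. Ddx3y and Eif2s3y reached at most 3 and 6 counts in a cell, so detection of Kdm5d or Uty cannot be read alone as the sex of a cell. The X-linked genes Ddx3x, Kdm5c and Kdm6a were detected in 74, 67 and 44 cells.

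Without the 18 dissociation stress genes, 24, 31 and 19 cells fell in clusters 1, 2 and 3. Of 17 measured members, 1 was higher and 3 were lower in cluster 1, among them the stress factor gene Atf3, 2 were lower in cluster 2 and 1 was higher in cluster 3. Hsp90aa1, Jun and Ier2 were the most abundant members and were detected in all cells, and Fosb was detected in 1. Of 11 measured members of the p53 and apoptosis list, Ccng1 was higher and Phlda3, Sesn2, Ddit4 and Bcl2l11 were lower in cluster 3, and Bcl2l11 was higher in cluster 1. Trp53, Bax and Mdm2 were detected in 74, 73 and 70 cells and Cdkn1a in 2. Of 15 glycolysis and hypoxia genes, Pfkp and Ankrd37 were higher in cluster 3. Ldha was at 4887 ± 2350, 6312 ± 1801 and 7256 ± 3125 CPM in clusters 1, 2 and 3, Gapdh and Eno1 were detected in all cells and Car9 in 10. Of 10 imprinted growth genes, Mest was at 4631 ± 1521 CPM in cluster 2, 2393 ± 1226 in cluster 1 and 888 ± 937 in cluster 3. Plagl1 was higher in cluster 1, Peg3 and Cdkn1c differed by less than 2-fold, and Dlk1 was detected in 61 cells. No mitochondrial or housekeeping gene differed by 2-fold in any cluster. Over all cells mt-Co3, mt-Atp6 and mt-Co1 were at 4070 ± 1575, 3085 ± 1397 and 2968 ± 1020 CPM, mt-Nd3 was detected in 73 cells, Eef1a1 and Ppia were at 5009 ± 962 and 3843 ± 607 CPM, and B2m was detected in 66 cells.

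Members of 18 of 29 lists varied together over the 74 cells beyond the 95th percentile of 10000 random lists matched on expression, which describes these cells and is not a test. The mean pairwise Spearman correlation was 0.716 for G2/M genes, 0.704 for mitochondrial genes, 0.486 for cardiomyocyte genes, 0.473 for S-phase genes and 0.234 for epicardial genes. It was 0.125 for Hox and positional genes, at the 100th percentile. Retinoic acid, Wnt, Notch and hedgehog genes had correlations of 0.00754, 0.00581, -0.00465 and 0.0277, at percentiles 55.2, 54.5, 32.0 and 75.5. BMP, FGF and Hippo genes were at percentiles 87.5, 83.7 and 88.7.

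Among genes detected in 10% to 90% of cells, the 25 that varied most above the trend included the mitotic genes Ccnb1, Ccna2, Cdk1, Ube2c, Top2a, Cdca8, Cdc20, Kif20a, Ccnb2 and Kif22, and the growth-arrest gene Gadd45g. Itm2a ranked highest, at 693 ± 934 CPM, followed by Pmp22 at 406 ± 391. The muscle genes Unc45b, Actc1 and Myl9, the epicardial-list genes Ezr, Podxl, Tcf21 and Krt18, and Col3a1, Smoc2, Ccn2, Sox9 and the chemokine receptor Ackr3 made up the rest.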

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

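The clusterings without cell 41, without cell 17, without pseudogenes, with each list or the regulators left out, without genes that follow the cycle or stress score, and those repeated at 3 clusters were chosen only after the results were seen. The minimum of 3000 genes removed no cell and so tests nothing. Of the lists left out, 8 held no variable gene, so these settings do not test the listed genes. Leaving out the endothelial or the p53 and apoptosis list still moved cells, with an adjusted Rand index of 0.936. Of 586 values under the other settings, 496 stayed within their interval or spread and 90 did not. These counts cannot be read as a measure of stability, because some outcomes were fixed in advance. Rank correlations of list members cannot change with a pseudocount of 10 CPM, and where 3 clusters were asked for their number cannot change. Conversely, a higher pseudocount raises list levels by itself. How many of the 586 values were fixed in these ways was not counted. The share of cells with at least 5 G2/M genes became 100% when 1 count made a gene detected, as a lower count can only add cells.

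The sizes of the clusters depended on the settings, and the cause was not tested. With scran size factors 2 clusters were found, and cluster 2 held 57 cells, with all 31 cells of the original cluster 2 among them. A pseudocount of 10 CPM gave 6 clusters, with 12 cells in cluster 1. Cluster 1 held 21 cells with 500 variable genes, 21 with 5 components and 20 with 20 components, each at 4 clusters. With 2000 variable genes 2 clusters were found. There cluster 1 held 64 cells and cluster 3 kept its 10, so the original clusters 1 and 2 were not separated. Without a filter on low counts clusters 1 and 2 held 73 and 1 cells, and at 3 clusters cluster 3 held 1. Each time the single cell was not from the original cluster whose number it took. At 3 clusters in this setting the cells of the original cluster 3 thus formed no cluster of their own. After thinning 2 clusters were found, matched to clusters 2 and 3, of 49 and 17 cells. At 3 clusters cluster 3 held 17 of the thinned cells. Cluster 1 held 17 cells without cell 41, 20 without cell 17 and 20 without pseudogenes, each at 4 clusters. Without the dissociation stress list, clusters 1 and 3 held 24 and 19 cells.

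At 3 clusters the adjusted Rand index with the clusters reported was 0.889 with a pseudocount of 10 CPM, 0.756 with scran size factors, 0.753 with k-means and 0.699 without a filter. With each of the 23 lists that held a variable gene left out in turn it had a median of 0.936 (range 0.755 to 1). When the genes were split at random into 2 equal sets, clusters from the sets had a median index of 0.787 with each other over 20 splits (range 0.308 to 0.888), against 0.0137 when each gene was shuffled over cells. No paired analysis was possible because the labels link no cells to embryos. Depth limits rare transcripts: 24.2% of thinned cells had 3 or more erythroid markers, against 37.8% before thinning.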

Other observations

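The tests of depth and cell cycle on single clusters, of cardiomyocyte reads, of globins and of the sinus venosus, and the control with random genes, were chosen only after the results were seen. So were the pairs of Sox10 with Erbb3 and of Wt1 with Actc1. Sox10 and Erbb3, genes of the neural crest and its glia, were detected together in 6 cells, against 1.51 under independence over all cells. All 8 cells with Sox10 lay in cluster 2, where Sox10 was at 5.87 ± 13.3 CPM and Erbb3 at 15.8 ± 27.0. Erbb3 was detected in 13 cells of cluster 2 and 1 of cluster 3. Shared membership of cluster 2 thus raises the number with both genes by itself, and independence within that cluster was not tested.

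Hcn4, a pacemaker channel gene of the cardiomyocyte list, was detected in 22 of 33, 3 of 33 and 7 of 8 cells of clusters 1, 2 and 3 rebuilt without that list. Shox2, a sinus node factor on no list, was detected in 25, 13 and 7 of the same cells. Wt1 and Actc1 were detected together in 35 cells, against 38.1 under independence.

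The grouping into 3 clusters was weighed against technical explanations, and no biological explanation was tested, since the labels give no groups. For cluster 2 depth was argued against at 3 clusters, since 88.46% of its thinned cells stayed in a cluster that held 0% of the others. The argument is limited to 3 clusters. At the 2 clusters that the rule chose after thinning, all 26 of its thinned cells shared a cluster with other cells. Without genes that follow the cycle score, 96.77% of cluster 2 cells stayed in a cluster that held 4.651% of the others at 3 clusters. That argued narrowly against the cell cycle for cluster 2 at 3 clusters. These others were 2 cells of cluster 1. The mark for their share, set after the results were seen, lay just above 4.651%. Depth stays open for cluster 1 against cluster 3, where 80% of thinned cells were placed as before and 8 cells of cluster 1 moved to cluster 3, and for the number of clusters, where the index after thinning was 0.2426, or 0.6021 at 3 clusters. The cell cycle stays open for cluster 1 against cluster 3, where 86.05% of cells were placed as before, and for all 3 clusters, with an index of 0.7407 without genes that follow the score and 0.829 without the listed S-phase and G2/M genes. Genes that follow the cycle score held 246 of the 1000 variable genes. Leaving out 246 random variable genes gave a median of 0.879 (range 0.645 to 0.967), which includes 0.7407. Dissociation stress stays open: the index was 0.9673 without genes that follow the stress score, but these held only 26 of the 1000 variable genes, 26 random variable genes left out gave a median of 0.967 (range 0.796 to 1), and leaving out the stress list gave 0.755.

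Cardiomyocyte transcripts outside cluster 3 could be reads carried over from its cells. One source would give all markers a like ratio, but in clusters rebuilt without the cardiomyocyte list the mean outside as a percent of that inside ran from 1.46% for Myh6 to 37.4% for Tnni1 over 12 markers. The highest ratio was 25.7 times the lowest (95% interval 10.6 to 86.2 over resampled cells), and 41.02 times in the clusters of all genes. This argues against carry-over as the whole cause and leaves it open for markers with low ratios, such as Myh6 and Csrp3. No biological explanation was tested.

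Adult globin transcripts were detected although the sort for the Tbx18 reporter would remove unlabelled red cells. Embryonic blood was argued against as the source, since embryonic beta-like globins were at 0.04639 of adult beta globins, or 0.06062 without cell 17, which had the most. One source of adult blood RNA may explain them and stays open: 85.29% of cells with Hbb-bs also had Hba-a2, against 60.81% of all cells. Mean levels were 48.3 CPM for Hba-a2 and 25.4 for Hbb-bs.

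A hypothesis is that cluster 3 may include sinus venosus myocardium, the inflow muscle in which Nkx2-5 is low. The rule needed Nkx2-5, Nppa and Gja5 each in under 20% of the cluster's cells and Hcn4, Shox2 and Tbx18 each in over 50%. Nkx2-5 or Nppa in 50% or more, or Shox2 in under 20%, was the mark for exclusion. Both marks apply to the cluster as a whole, so they cannot exclude that a part of its cells is such muscle. Nkx2-5 was detected in 40% of the 10 cells (interval 12.2% to 73.8%), which lies between its 2 marks. In clusters rebuilt without the cardiomyocyte list it was detected in 50% of 8 cells (interval 15.7% to 84.3%), which meets the mark for exclusion of the cluster as a whole. The readings differ and both intervals span both marks, so the hypothesis stays open. In those 8 cells Nppa and Gja5 were detected in 0, and Hcn4, Shox2 and Tbx18 in 7, 7 and 5.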
